A study of Homo sapiens with 20 samples.

How the data were processed

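RNA of 20 liver cancer cell lines was hybridised to 2-colour Agilent whole human genome arrays with 45015 spots, of which 43376 held one of 41000 probes and 153 were negative controls; 264 probes were spotted 10 times. Per the labels, total RNA was extracted with a Qiagen RNeasy kit and labelled by Quick-Amp, with the line in Cy5 and the reference mix in Cy3 on every array, so no dye swap exists. The lines lay on 6 slides: JHH2, JHH4, JHH5 and JHH6; JHH7, HLE, HLF and HUH1; HepG2, SNU182, SNU387 and SNU398; Hep3B, SNU423, SNU449 and SNU475; PLC/PRF5, HUH7 and SKHep1; and JHH1 on a slide of its own, scanned on another of the 2 scan days. The labels give the reference mix under differing names, and which applies could not be settled from the files; all 20 arrays were treated as having the same reference.

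Per the file headers, the authors read the scans with Agilent Feature Extraction 9.5.1, with background subtraction off and the software's own linear and lowess dye normalization. The deposited scanner files give intensity, as the mean pixel intensity of each spot, the median intensity of its local background and the dye-normalized processed intensity, in each channel. The deposited LogRatio is the log10 of the processed Cy5 intensity over the processed Cy3 intensity. The deposited series matrix holds the same log10 ratio: 99.5% (Hep3B) or more of its values were within 0.0001 of the mean LogRatio of the probe's spots on each array, and its column medians were 0.00761 (PLC/PRF5) to 0.0216 (JHH5). The scale, direction and centring of the matrix are therefore known, but it holds no channels.

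Signals were corrected with normexp (limma 3.58.1 in R 4.3.3; spot mean, background median, offset 50) and ratios were normalized within arrays by loess (span 0.3). limma's default normexp fit over all spots gave negative background means, down to -1198 (HUH1 line channel), where a few spots lay below their local background. The fit was therefore made on the spots above their local background (background means 0.459 to 19.8). On each array 0 to 31 spots that were not above it in the line channel, the reference channel or both were set missing. This choice was made after the fits, and the counts, list scores and correlations they gave, had been seen; the default fit is among the alternatives. Channels were made comparable between arrays by Aquantile. Spots of 1 probe were averaged. Probe names were matched to current gene symbols by accession, symbol or synonym; 26680 probes had 1 usable gene. Probes naming no gene or several, LOC names, XIST, TSIX and Y-linked genes were left out. Coordinates are those of the files, in build hg17.

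The deposited flag for signals well above background was 1 for 100% of spots on every array, negative controls included, and was not used. A spot was called well above background when its signal exceeded the median of the negative controls by 13 (the multiplier in the file header) times their MAD scaled by 1.4826, per array and channel. A probe passed when it was well above background in the line channel on at least 2 arrays or in the reference channel on at least 10; 21461 probes and 14431 genes passed. A gene was read from its passing probe of highest mean signal. Of 5323 genes with more than 1 passing probe, 22.6% had a pair of probes whose correlation over lines was under 0.5. Where the line was not well above background, a value is given as a bound: the reference signal over the larger of the dim signal and the lowest signal well above background on that array.

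With 1 array per line, the reference channel, which holds the same RNA on 20 arrays, served as the technical error. Genes varying between lines were found by the Pitman-Morgan test, one-sided, of the variance of the line channel against that of the reference channel. All adjusted p-values are Benjamini-Hochberg with a threshold of 0.05. List scores (23 lists) are medians of log2 ratios; their spread was set against 10000 random lists of the same size in 50 bins of mean signal. Relations are Pearson and Spearman correlations with two-sided permutation p-values (100000 permutations, or exact for 7 lines), adjusted over 55 relations. Genes shared by 2 lists were left out of both. With each slide centred, the centred values were permuted over all lines without allowing for the slide means removed, so those p-values are too small. A score was taken to fall into separate groups when a mixture of 2 Gaussians exceeded 1 by a BIC of at least 10, with at least 3 lines each and a gap larger than any within a group; r was then given only within groups of at least 6 lines. Association with a score was fitted by limma (lmFit and eBayes), lists by camera with a preset correlation of 0.01 and with an estimated one, and slides by limma's F test on 19 arrays. The gene counts of the associations and slide tests, but not the lists, were set against 100 permutations. In the limma fits and principal components missing values (0.103% of all) were replaced by the gene's median or the gene was left out. Software included Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

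The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule named the 25 genes of largest SD among those that varied, for each line the gene exceeding the second-highest line by most, the 12 genes rising and the 12 falling most with the hepatocyte score (none passed), the 4 of largest SD in each list and the members of the gene pairs. Not every gene that the rule names is given in the text. Other genes in the text were chosen after their values were seen.

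The tests were run on simulated data in which known changes were added. With both channels given the same technical SD, the test of variance recovered 94% of genes with an added SD of 1 and 44% at 0.25. The fit to the score recovered 56% of genes with a slope of 2 (log2 per unit of score) within 13 lines and 46% within 7 lines. It recovered 100% with a slope of 1 over 20 lines, fitted to the score of hepatic transcription factors. The plasma protein score ran from -3.84 to -2.48 in the 13 lines and from 0.21 to 1.76 in the 7. The transcription factor score ran from -2.84 to 1.25, a wider range, so these figures cannot be set beside each other. In these fits the simulated noise of a gene had its SD over all 20 lines. That SD includes any difference between the 13 and the 7 lines, so recovery in the real fits within them may differ. Of 200 random lists, 4.5% exceeded the 95th percentile of spread, and 0% of samples simulated from a single Gaussian were split in 2. The slide test recovered 8% of genes with a difference of 1 in the ratio and 90% in the reference channel.

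Alternatives were the scanner's processed signals without loess, median centring in place of loess, no background subtraction, no filter, a strict filter requiring 10 arrays in the line channel, the mean over probes, the series matrix, the list mean in place of the median, slide centring or a slide term, other tests, and each line left out in turn. The normexp fit on all spots, a multiplier of 2.6, the panel without PLC/PRF5 and JHH1, and the sum of the lines from the series matrix were added after the data had been seen. Leaving out a line kept the filter and the Aquantile scaling of all 20 arrays. The series matrix has no channels, so the test of variance and the slide test of the reference channel were not run on it.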

Results

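Gene expression was measured in 20 established cell lines of human liver cancer: Hep3B, HepG2, HLE, HLF, HUH1, HUH7, JHH1, JHH2, JHH4, JHH5, JHH6, JHH7, PLC/PRF5, SKHep1, SNU182, SNU387, SNU398, SNU423, SNU449 and SNU475. Each line was a group of 1 array, so no value for a line has a replicate and no p-value is given for a line. On every 2-colour array the line was labelled with Cy5 and a common reference with Cy3. Per the labels, the reference was a mix of equal amounts of RNA from 19 of the lines, all except JHH1. All values below are log2 ratios of a line to that mix, so 0 means the level of the mix, 1 means 2-fold higher and -1 means 2-fold lower. The median signal was 1.24 (PLC/PRF5) to 6.48 (JHH1) times that of the negative control spots in the line channel, and 1.35 (PLC/PRF5) to 4.06 (JHH1) times in the reference channel. Between 34.8% (PLC/PRF5) and 67.1% (JHH1) of the probe spots were well above background in the line channel. The number of arrays limits the precision. Per the series description, the lines were profiled to set them beside liver tumours; the tumours are not part of these files.

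The question of the comparison of channels was how far the lines differed from each other beyond technical variation. Of 14431 genes, 13895 (96.3%) varied more between the lines than the same reference RNA varied over the same 20 arrays (Pitman-Morgan test, one-sided, adjusted p under 0.05). At an unadjusted p under 0.05, 13901 genes did. With no filter on dim probes the test called 15775 of 17431 genes, more than the 14431 that passed the filter. It therefore also called genes too dim for the filter, and a call does not by itself show that a gene was detected. Each line was measured once, so the test sets differences between lines, which include those between cultures, against the technical variation of the reference channel alone. The line was always in Cy5 and the reference in Cy3, so any greater technical variation of Cy5 counts as a difference between lines. The median SD over 20 arrays was 0.65 in the line channel and 0.17 in the reference channel, and the line channel had the larger SD in 99.5% of the genes. The log2 ratio had an SD of at least 1 in 2931 genes and of at least 2 in 412 genes. Repeated spots of 1 probe on 1 array had a median SD of 0.0666, and of 0.109 on the PLC/PRF5 array.

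**Figure D1:**
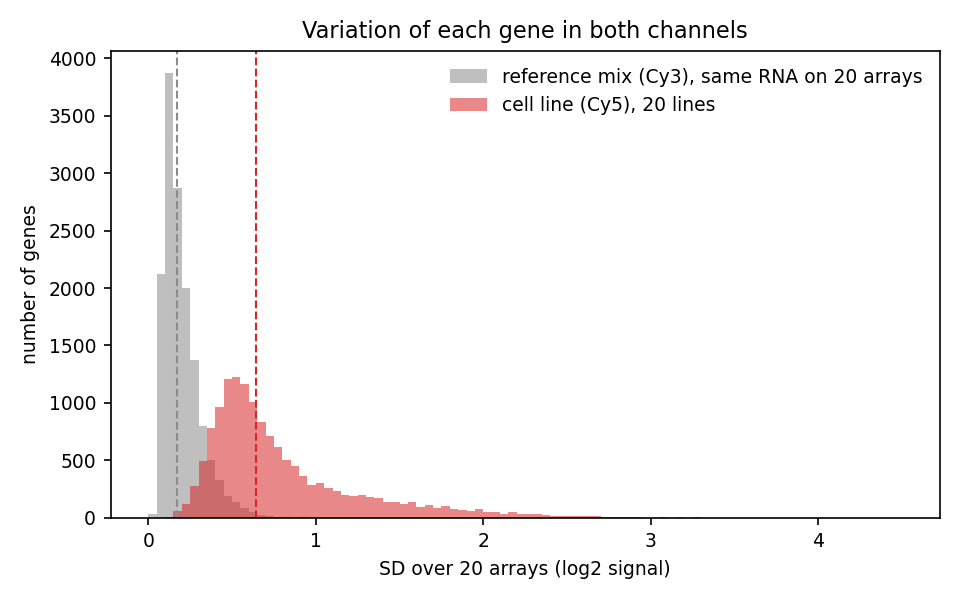
Number of genes (y axis) by the SD of their log2 signal over 20 arrays (x axis), for the reference mix (grey) and the cell lines (red); dashed lines are the medians, 0.17 and 0.65. The reference channel holds the same RNA on all 20 arrays.

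Genes of differentiated hepatocytes were among those that varied most. ALB, which encodes serum albumin, had the largest SD of all genes (4.36; probe A_23_P257834, chromosome 4, 74650377 to 74651050, build hg17, reference channel SD 1.13). It was 3.83 in Hep3B, 2.35 in HUH7, 1.63 in JHH5 and 1.44 in HUH1, and -8.03 in SKHep1, the lowest line. Other secreted plasma proteins were among the 25 genes of largest SD: APOH (SD 3.87), AHSG (3.85), FGG (3.33), FGB (3.26), TTR (3.03), TF (2.96) and A2M (3.29). AFP, the fetal albumin homologue used as a tumour marker (SD 3.30; probe A_23_P58205, chromosome 4, 74680215 to 74680842), was highest in HUH7 at 4.39 and stood at 1.15 in HepG2, 1.17 in JHH5 and 0.25 in JHH7. The pioneer factor FOXA2 (SD 3.14) was 1.37 in Hep3B and at least 99.3-fold lower than the mix in HLE.

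Outside the hepatocyte genes, several of the 25 most variable genes were present in some lines and nearly missing from others. GSTP1, a glutathione transferase (SD 3.31; probe A_23_P202658, chromosome 11, 67110626 to 67110685), was highest in HUH7 (4.09) and SNU475 (3.17), and lowest in JHH4 (-5.55). LDHB, a subunit of lactate dehydrogenase (SD 3.22), was 2.96 in JHH4 and -5.85 in SNU398. MTHFD2, an enzyme of mitochondrial folate metabolism (SD 3.30; probe A_23_P120316, chromosome 2, 74353640 to 74353699), was highest in SNU398 (1.74), and in JHH2, JHH4, JHH6 and SNU387 it was not well above background, in JHH2 at least 56.5-fold below the mix. The surface proteins EPCAM (SD 3.22), highest in JHH1 at 3.92, and CD44 (SD 2.94), highest in HLE at 2.09, were also among them. So were the chemokine receptor ACKR3 (2.77 in JHH2), the neuropeptide NMU (5.30 in JHH1), the nuclear receptor NR0B1 (3.38 in JHH6, 2.74 in HUH1 and 2.15 in SNU475), the collagen COL11A1 (2.92 in SNU449), the matrix protein EFEMP1 (2.89 in SNU182), GNG11 (1.89 in JHH1), the growth factor binding protein IGFBP1 (4.09 in PLC/PRF5), TM4SF4 (3.47 in Hep3B) and the trypsin inhibitor SPINK1 (2.81 in JHH7).

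For 23 gene lists, the score of a line was the median log2 ratio of the list. The score spread over the 20 lines more than in 95% of random lists of like signal for 21 lists, all but the endothelial (87.5th percentile) and leukocyte (33.3th percentile) markers. The stable control genes fell below the 95th percentile with the mean over members (90.5), without JHH2 (94.5) and without SNU398 (92.1), and the dasatinib targets under a filter requiring 10 arrays (94.7). Of the list members measured, the counts that varied between lines were the same over all genes as adjusted over the list alone for each of the 23 lists. Members counted as varying included genes that were dim in most lines. LCK, DES and LRAT were not well above background in either channel in 18 of the 20 lines, and GAGE1, TAT and SLCO1B1 in 17.

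Plasma protein genes of hepatocytes divided the panel into 7 lines with a score above the mix and 13 far below it. All 27 of the 27 measured members varied between lines. The score was 1.76 in HUH7, 1.58 in Hep3B, 1.36 in HepG2, 1.20 in HUH1, 0.49 in PLC/PRF5, 0.39 in JHH5 and 0.21 in JHH7. The other lines lay between -2.48 (SNU449) and -3.84 (SNU475). A mixture of 2 groups fitted this score better than 1 group by 28.8 units of BIC, where 10 had been required. Members at least 2-fold above the mix numbered 19 in Hep3B, 17 in HUH7, 16 in HepG2 and 15 in HUH1. In HLF, JHH6 and SNU475 all 27 members were at least 2-fold below it. PLC/PRF5 was split within the list, with 11 members at least 2-fold above and 10 at least 2-fold below the mix, a mean of -0.29 against the median of 0.49, and ALB at least 148-fold lower than the mix. Because the score was in 2 separate groups that it defined itself, no test was made between them. No correlation of this score was pooled over them.

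**Figure D2:**
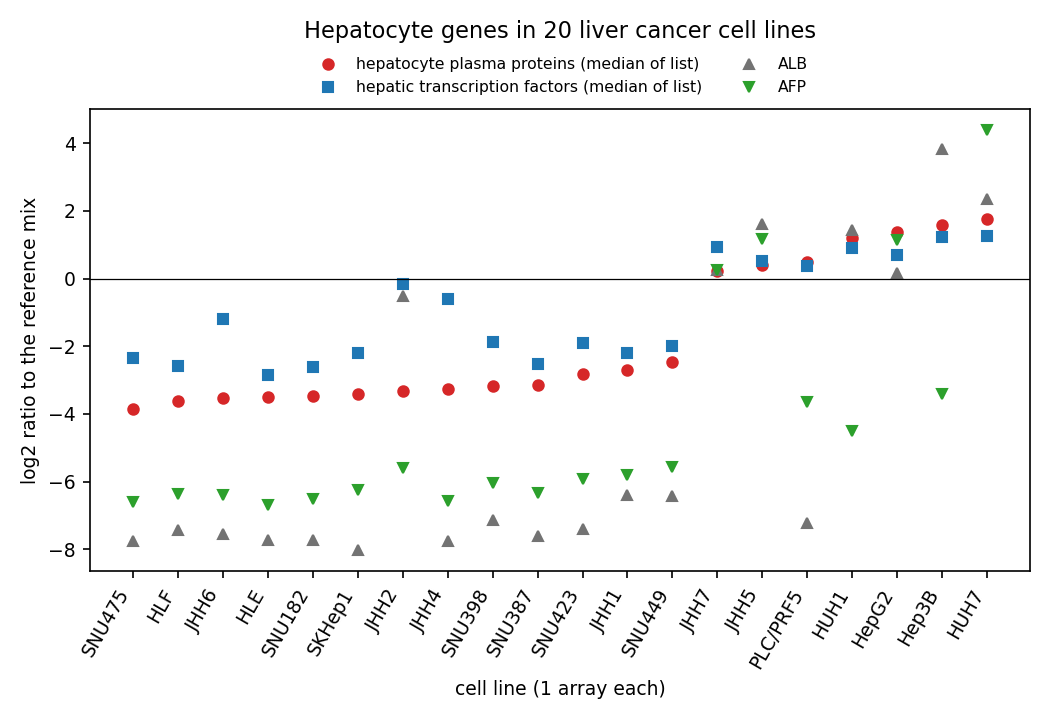
Log2 ratio to the reference mix (y axis) of the hepatocyte plasma protein score (circles), the hepatic transcription factor score (squares), ALB and AFP (triangles; not well above background for ALB and AFP in PLC/PRF5 and AFP in JHH4) in each of the 20 cell lines (x axis, 1 array each, ordered by the plasma protein score). The 7 lines on the right have plasma protein scores from 0.21 to 1.76 and the 13 on the left from -3.84 to -2.48.

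The other hepatocyte lists followed the plasma proteins in part. The score of the hepatic transcription factors was 0.39 (PLC/PRF5) to 1.25 (HUH7) in the 7 lines and -2.84 (HLE) to -0.15 (JHH2) in the 13, and 14 of 15 measured members varied between lines. FOXA1 was 1.86 in Hep3B and at least 33.4-fold lower than the mix in SNU387, and CREB3L3 reached 2.68 in HUH1. HNF4A was too dim to be measured. JHH2 and JHH4 had low plasma protein scores (-3.32 and -3.27) with FOXA2 near the mix (-0.66 and -0.73). The metabolic enzymes of hepatocytes scored highest in HUH1 (1.31; 13 of 23 members at least 2-fold higher), where the urea cycle genes CPS1 and OTC were 2.63 and 3.26 and the tyrosine enzyme HPD was 4.03. In HUH7 the urea cycle gene ARG1 was 3.26, and in PLC/PRF5 CPS1 was 3.74. The metabolic score was -0.45 in Hep3B (3 members at least 2-fold higher and 9 lower), 0.0078 in HUH7 and 0.0051 in PLC/PRF5, and in HUH7 and PLC/PRF5 its sign changed between settings. All 23 measured members varied between lines, with UGT2B4, ARG1 and HGD among those that varied most. Among fetal and progenitor markers (all 16 measured members varied), the score was highest in Hep3B (0.67) and lowest in JHH6 (-2.76). It was also below 0 in HUH1 (-1.60), PLC/PRF5 (-1.01) and JHH7 (-0.51, but above 0 with median centring and under the strict filter), lines of high plasma protein score. GPC3, a tumour antigen of the fetal liver, was 2.82 in HepG2, 1.73 in Hep3B, 1.74 in HUH7, 1.29 in JHH5 and 1.28 in HUH1, where 12 of the 16 members were at least 2-fold lower and 1 was higher. The imprinted pair IGF2 and H19 was high together in Hep3B (2.80 and 3.21), whereas JHH7 had IGF2 at 1.64 with H19 at -2.0. Over the 20 lines IGF2 and H19 had r = 0.582 (permutation p = 0.0131, adjusted p = 0.144) and rho = 0.660 (p = 0.00205, adjusted p = 0.0282). After each slide was centred r was 0.614 (permutation adjusted p = 0.0486 over 32 relations). That p-value did not allow for the slide means removed and is too small, so it does not settle the relation. Without the 2 lines farthest from the IGF2 median r was 0.290, so Pearson's r rests on those lines; rho was not computed without them. Without JHH5 r was 0.727 (permutation adjusted p = 0.00935).

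The next question was which genes go with the degree of hepatocyte differentiation. Within the 13 lines of low score no gene was associated with the plasma protein score (limma, adjusted p under 0.05; 610 genes at an unadjusted p under 0.05; 33 genes passed under limma's default normexp fit), and within the 7 lines of high score none was (710 genes). Spearman correlation gave 0 and 0 genes (760 and 801 at an unadjusted p under 0.05), of which the second says little, since with 7 lines many genes would need a perfect rank order for any to pass. Some lists moved along the score as sets under camera with a preset correlation of 0.01, and none of these calls held with an estimated correlation. No member of these lists passed on its own; adjusted over the list alone 4 cancer-testis genes and 1 epithelial gene did within the 13 lines, 3 cholesterol synthesis genes did within the 7 lines, and none did in the other calls. Within the 13 lines, the cancer-testis list was lower with a higher score (adjusted p = 1.93e-09, or 0.157 with an estimated correlation; median slope -1.94) and the epithelial list higher (adjusted p = 4.53e-06, or 0.517; median slope 0.81). Bile duct markers and metabolic enzymes were higher and the dasatinib target kinases lower (adjusted p = 0.0236 each). With an estimated correlation these had adjusted p = 0.169 for the bile duct markers, adjusted p = 0.517 for the metabolic list and adjusted p = 0.157 for the dasatinib list. With slide as a block the epithelial (adjusted p = 0.141), dasatinib (adjusted p = 0.0825) and bile duct (adjusted p = 0.0891) calls were lost. Under limma's default normexp fit the cancer-testis (adjusted p = 0.257), dasatinib (adjusted p = 0.257) and bile duct (adjusted p = 0.422) calls were lost. With median centring the metabolic (adjusted p = 0.601) and dasatinib (adjusted p = 0.0829) calls were lost. The dasatinib call was also lost with the mean over members (adjusted p = 0.0578) and the mean over probes (adjusted p = 0.0673), the bile duct call with the mean over probes (adjusted p = 0.208) and the metabolic call under the strict filter (adjusted p = 0.0595). Without JHH1 the epithelial (adjusted p = 0.311), bile duct (adjusted p = 0.141) and dasatinib (adjusted p = 0.106) calls were lost. Without SNU475 the bile duct, dasatinib (adjusted p = 0.105 for both) and metabolic calls (adjusted p = 0.0581) were lost. The metabolic call was also lost without HLF, SNU423 or SNU449 (adjusted p = 0.058, 0.0615 and 0.171), and the bile duct call without SNU449 (adjusted p = 0.0638). Without JHH4 1 gene was associated with the score. Within the 7 lines 6 lists moved with the score at the preset correlation, and with an estimated one all 6 had adjusted p = 0.784. The cholesterol synthesis list (adjusted p = 1.01e-10, median slope 1.13), the cell cycle list (adjusted p = 6.02e-07, median slope 0.52), the hepatic transcription factors (adjusted p = 0.0473) and the fetal and progenitor markers (adjusted p = 0.0485) were higher with a higher score. The cancer-testis list (adjusted p = 0.00216) and NRF2 targets (adjusted p = 0.0141) were lower. Without PLC/PRF5, Hep3B or HUH7 3 lists in all passed. The cancer-testis call was lost without PLC/PRF5 (adjusted p = 0.446), and that of NRF2 targets without Hep3B, HUH7 or JHH5 (adjusted p = 0.49, 0.351 and 0.28). The transcription factors were lost without any of Hep3B, HUH1, HUH7, JHH5 or PLC/PRF5 (adjusted p = 0.0562 to 0.446), and the fetal markers without Hep3B, HepG2, HUH7 or PLC/PRF5 (adjusted p = 0.0917 to 0.49). With slide as a block the fetal markers were lost (adjusted p = 0.221), and the median t of the NRF2 targets was above 0 (0.46, adjusted p = 0.127). Among the 7 lines only HUH1 with JHH7 and HUH7 with PLC/PRF5 share a slide, so the slopes with slide as a block rest on these pairs alone. That fit also gained calls for the metabolic and NF-kB lists. The NRF2 call was also lost with the mean over members (adjusted p = 0.0787) and with median centring (adjusted p = 0.604). That of the transcription factors was lost under the strict filter (adjusted p = 0.156). The fetal markers were lost with no filter (adjusted p = 0.0718), a multiplier of 2.6 (adjusted p = 0.0696) and the series matrix (adjusted p = 0.0561).

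The score of the hepatic transcription factors, an alternative measure of differentiation, did not divide into separate groups by the same rule (9.21 units of BIC) and could be fitted over all 20 lines. It was associated with 1067 genes (limma, adjusted p under 0.05), 648 rising and 419 falling with it, although the 7 and the 13 lines did not overlap in this score either. The genes with the largest moderated t were chosen after these values were seen. They included AGMAT (slope 1.40 per unit of the score, adjusted p = 1.47e-06), the APOB editing cofactor A1CF (1.19), the brush border protein VIL1 (1.68), the complement protein C5 (1.36), the asialoglycoprotein receptor subunit ASGR2 (1.66) and the hepatocyte gap junction protein GJB1 (1.11). Those falling included OSBPL5 (slope -0.98, adjusted p = 1.8e-05), the matrix cross-linking enzyme LOXL1 (-1.42), CYBRD1 (-1.23) and the cytokine signalling inhibitor SOCS3 (-0.92). Of the metabolic enzymes of hepatocytes, 11 of 23 rose (20 adjusted over the list alone) and none fell (camera adjusted p = 4.41e-14; adjusted p = 0.0206 with an estimated correlation). Of the mesenchymal genes, 10 of 27 fell (16 adjusted over the list alone) and none rose (adjusted p = 2.81e-09; adjusted p = 0.108 with an estimated correlation). Of the YAP target genes 8 of 19 fell and none rose (adjusted p = 4.59e-05; adjusted p = 0.113 with an estimated correlation).

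The epithelial junction genes (all 22 measured members varied) scored highest in JHH1 at 1.83, with 16 members at least 2-fold above the mix. There CDH1, which encodes E-cadherin, was 4.16, CLDN3 was 3.97 and ESRP2 was 1.90, although the plasma protein score of JHH1 was -2.70. Hep3B followed at 0.84, and SNU475 (-1.44) and HLE (-1.33) were lowest. CDH1 was at least 30.2-fold lower in SNU475 and at least 25.2-fold lower in JHH6, lines in which it was not well above background. The mesenchymal genes (all 27 measured members varied) scored highest in SNU387 (0.87), SKHep1 (0.46), SNU475 (0.43), SNU423 (0.33) and JHH2 (0.28), and lowest in HUH1 (-2.58). The means of the list in SKHep1 (-0.21), SNU475 (-0.0031) and JHH2 (-0.45) were below 0. SPARC, a matrix protein, was 2.35 in SNU387, and VIM, the intermediate filament vimentin, was 1.81 in JHH2. CAV1, of caveolae, was 1.58 in SNU449 and VIM was 1.38 in SNU398, although the mesenchymal scores of these lines were below 0 (-0.73 and -2.09).

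The mesenchymal score rose with the score of genes induced by TGF-beta (r = 0.826, rho = 0.820, n = 20 lines; permutation p = 1e-05 for both, the smallest that 100000 permutations can give, adjusted p = 0.00055 for both). All 13 TGF-beta genes varied between lines; they scored highest in SNU182 (1.12) and JHH2 (0.92), with THBS1 at 2.33 in JHH2 and INHBA at 2.03 in SNU182. It also rose with the score of the YAP target genes (r = 0.690, permutation p = 0.00103, adjusted p = 0.0266; rho = 0.693, p = 0.00091, adjusted p = 0.0167). Those scored highest in SKHep1 (0.80), and the YAP targets CCN1 and ANKRD1 were 1.1 and 3.32 in SNU423. CDH1 fell as ZEB1, its transcriptional repressor, rose (r = -0.665, permutation p = 0.00145, adjusted p = 0.0266; rho = -0.699, p = 0.00072, adjusted p = 0.0167). ZEB1 was dim, well above background in the line channel on 10 arrays and in the reference channel on 7. CDH1 was not well above background in 6 lines, so its values there are bounds. All 3 relations pool the 7 lines of high and the 13 of low hepatocyte score. The mesenchymal, TGF-beta and YAP scores ran lower in the 7 (-2.58 to -1.56, -1.52 to -0.53 and -1.75 to -0.62). In the 13 they were -2.09 to 0.87, -1.36 to 1.12 and -0.84 to 0.80. Part of the r between these scores is therefore the difference between the groups, and r within the groups was not computed. Without the 2 lines farthest from the median r was 0.799, 0.721 and -0.508 for these 3 relations, and after each slide was centred (19 arrays) 0.839, 0.718 and -0.625. Slides held 3 or 4 lines each, too few for a value within a slide. These were the 3 of 55 relations computed whose Pearson r had an adjusted p under 0.05; by rho IGF2 and H19 passed as well. The call for YAP targets was lost without Hep3B (adjusted p = 0.0553), HUH1 (adjusted p = 0.0614) or SKHep1 (adjusted p = 0.0585), and under the default normexp fit (adjusted p = 0.0633). That for CDH1 and ZEB1 was lost without JHH1 (r = -0.562, permutation adjusted p = 0.204), and without Hep3B, JHH4, JHH6 or SNU475 (adjusted p = 0.055 to 0.0675). CDH1 and VIM had r = -0.237 (permutation p = 0.31, adjusted p = 0.844) and rho = -0.150 (p = 0.524, adjusted p = 0.93). Within the 13 lines of low AFP and low ALB, AFP and ALB had r = 0.453 (permutation p = 0.139, adjusted p = 0.537) and rho = 0.747 (p = 0.00456, adjusted p = 0.0502); r was 0.749 without 2 lines, 0.763 with each slide centred (adjusted p = 0.0339), -0.029 with median centring of arrays, 0.912 with the mean over a gene's probes (adjusted p = 0.00137) and 0.841 without PLC/PRF5 (adjusted p = 0.0208). The adjusted p of AFP and ALB with each slide centred did not allow for the slide means removed and is too small. Without Hep3B 1 relation in all had an adjusted p under 0.05, and without PLC/PRF5 5 had.

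**Figure D3:**
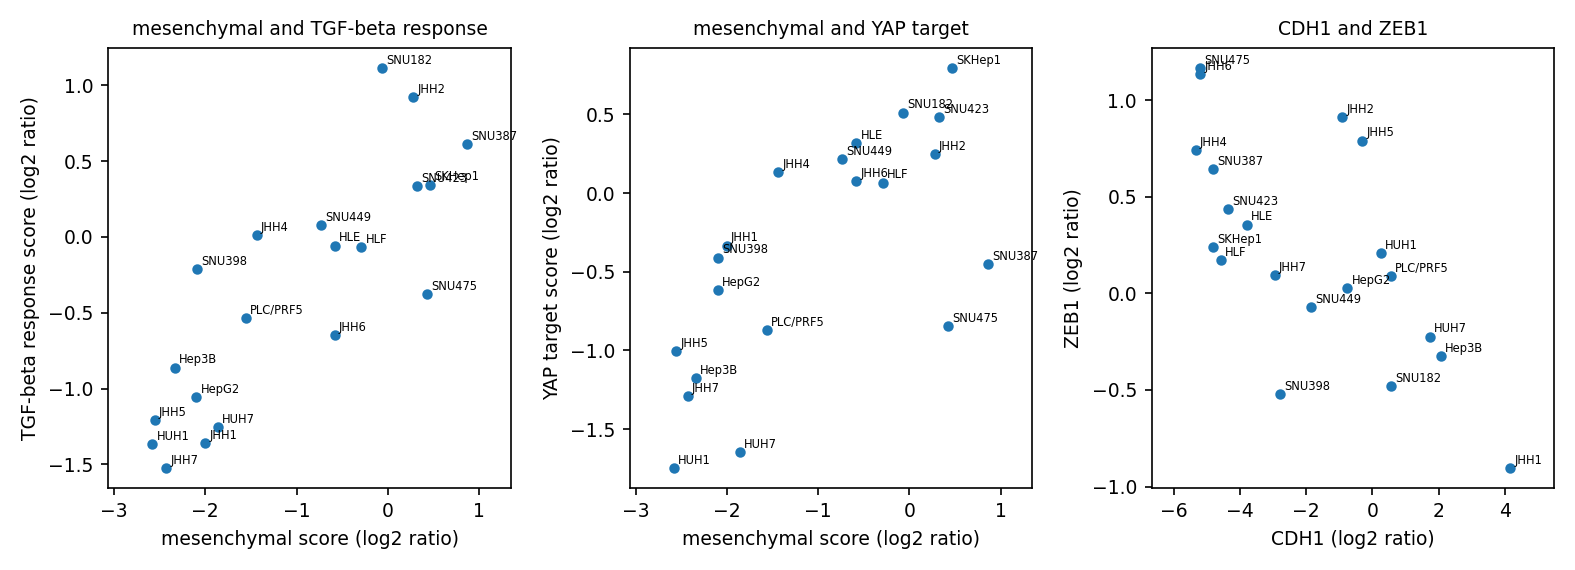
Scores or log2 ratios to the reference mix of 20 cell lines (points, 1 array each): TGF-beta response against mesenchymal score (left, r = 0.826), YAP targets against mesenchymal score (middle, r = 0.690) and ZEB1 against CDH1 (right, r = -0.665). Both axes of each panel are in log2 units. Each r is pooled over the 7 lines of high and the 13 of low plasma protein score.

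Lists of signalling and stress pathways singled out individual lines. Beta-catenin targets scored highest in HepG2 at 1.66, with 11 of 16 members at least 2-fold higher, among them NOTUM (3.42), NKD1 (3.20), RNF43 (3.0) and AXIN2 (1.47), all feedback regulators of the pathway. In SNU398 AXIN2 was 2.25 and LEF1 3.24, while the list score was -0.22. In all, 15 of the 16 members varied between lines. Cytokines and NF-kB targets scored 2.14 in SKHep1, where 13 of 15 members were at least 2-fold higher, among them CXCL1 (4.26), IL1B (4.0), CXCL8 (3.79) and IL6 (3.69). Their lowest score was -3.04 in SNU398, and all 15 varied. Genes induced by type I interferon scored 1.27 in HLF, with 11 of 16 members at least 2-fold higher (IFI44 2.49, IFI44L 2.56, OASL 2.47), and -1.69 in Hep3B. IRF7, in the same list, was -2.82 in HLF. NRF2 targets scored 1.79 in HUH1, with 15 of 17 at least 2-fold higher, 1.1 in JHH5, 0.65 in JHH6 and 0.48 in SNU475. The aldo-keto reductase AKR1B10 was 3.03 in JHH5 and 2.24 in HUH1. All 17 NRF2 targets and all 16 interferon genes varied.

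Metabolic and growth lists also differed between lines. Cholesterol synthesis genes (all 16 varied) scored 1.25 in HUH7 and 1.16 in Hep3B, with 10 and 10 members at least 2-fold higher, and HMGCS1 at 3.19 and 2.59. Within the 7 lines this score had r = 0.814 with the plasma protein score (exact permutation p = 0.0187, adjusted p = 0.171; rho = 0.857, exact p = 0.0238, adjusted p = 0.187; 0.749 without 2 lines; permutation adjusted p = 0.0437 with the mean over a gene's probes). Hypoxia genes (all 14 varied) scored 0.97 in SKHep1 and -1.25 in SNU398, where the genes used as stable controls also scored low (-0.98). The glucose transporter SLC2A1 was 3.76 in HepG2. S phase and mitosis genes (all 24 varied) were lowest in SKHep1 at -1.60, with 17 members at least 2-fold lower, and in PLC/PRF5 at -1.0. In SKHep1 the mitotic genes CENPF, UBE2C and CDK1 were -2.67, -2.39 and -2.37. They were highest in JHH2 at 0.44. Cancer-testis antigens (all 14 varied) scored 1.0 in HLF, 0.63 in PLC/PRF5 and 0.59 in SNU475, and below -2 in 9 lines. PAGE2 was 2.63 in HLF and 2.46 in HLE. Within the 13 lines of low hepatocyte score their score had r = -0.666 with it (permutation p = 0.013, adjusted p = 0.144). The rho was -0.681 (permutation p = 0.0121, adjusted p = 0.111). Without 2 lines r was -0.562, and with each slide centred -0.739 (permutation adjusted p = 0.0486 over 32 relations). That last p-value did not allow for the slide means removed and is too small.

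Kinases and receptors that are drug targets also differed. The score of SRC family and other kinases bound by dasatinib had an SD of 0.31 over lines, and all 16 measured members varied. LCK and FGR, counted among them, were not well above background in either channel in 18 and 16 lines. The score was highest in HLE (0.38) and SNU475 (0.30) and lowest in HUH1 (-0.80). DDR2 was 1.54 in HLF, 1.52 in SNU398 and 1.33 in SNU475. KIT was 2.40 in SNU182, 1.77 in HLF and 1.74 in HLE. FYN was 1.68 in HepG2. PDGFRB was 1.96 in HLF. Among receptor tyrosine kinases and ligands (all 18 varied), FGFR3 was 2.15 in Hep3B and 1.87 in HepG2, and AXL was 1.47 in JHH4. FGF19, a growth factor, was 2.61 in JHH7, and MET, the receptor of HGF, was -6.38 in SNU398. FGF19 and MET were chosen after their values were seen.

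**Figure D4:**
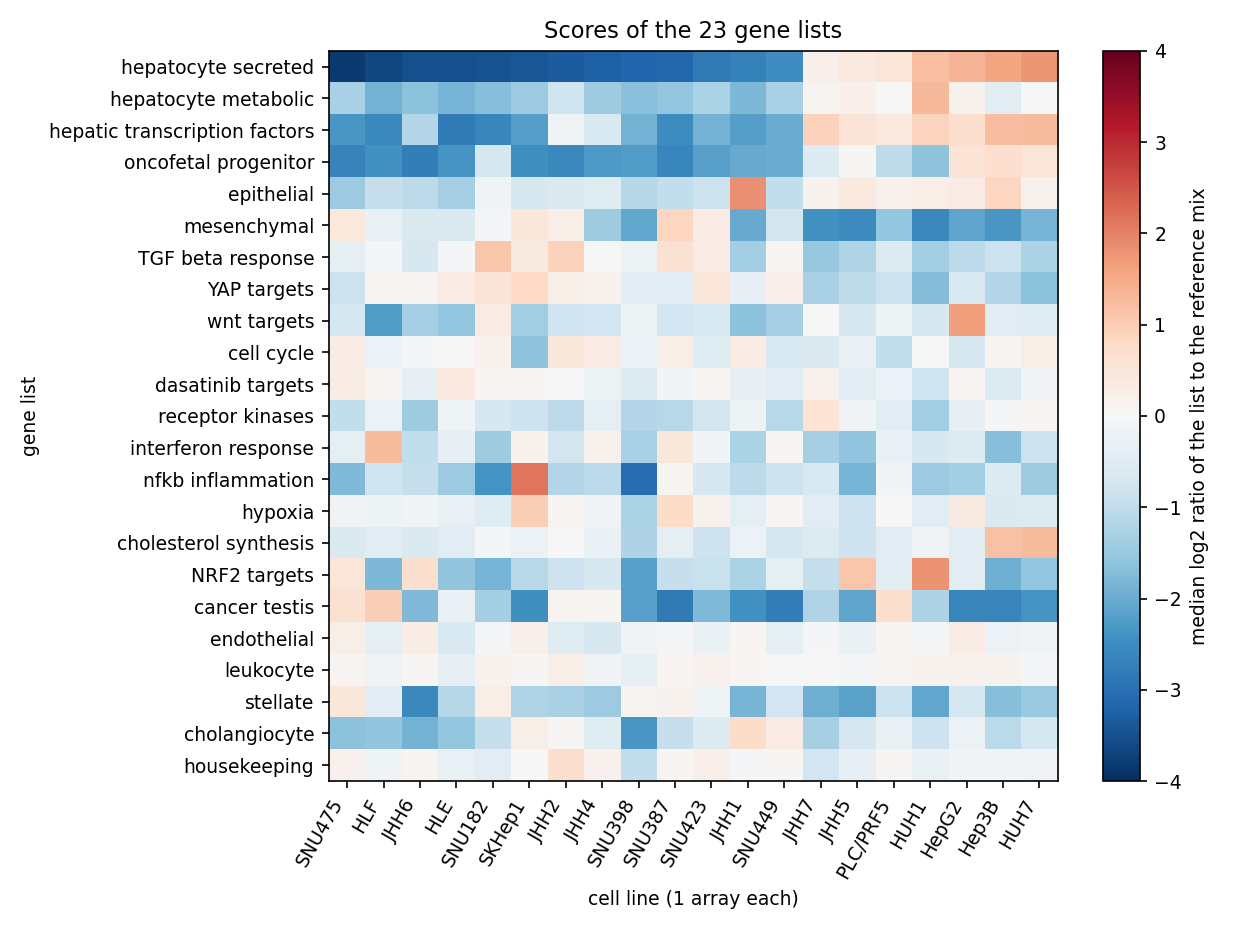
Scores of the 23 gene lists (rows) in the 20 cell lines (columns, 1 array each, ordered by the plasma protein score); colour is the median log2 ratio of the list to the reference mix. The NF-kB list reaches 2.14 in SKHep1 and the epithelial list 1.83 in JHH1.

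Markers of other cell types of the liver were measured in the same way. Stellate cell and fibroblast markers (all 12 varied) scored 0.45 in SNU475 and -2.57 in JHH6, and COL3A1 and LUM were 2.74 and 2.33 in SNU182. Bile duct markers (all 9 varied) scored 0.72 in JHH1, where MUC1 and ANXA4 were 2.70 and 2.67, and -2.31 in SNU398. SPP1 was 3.28 and KRT19 1.96 in JHH4. Endothelial scores stayed between -0.65 (JHH4) and 0.31 (JHH6, or -0.041 with no filter on dim probes), although TEK was 3.79 in SNU182 (all 10 measured members varied). Leukocyte scores stayed between -0.41 and 0.26, although LYZ was 4.22 in HepG2 (9 of 10 varied). The genes used as stable controls scored lowest in SNU398 (-0.98), where 6 of 12 were at least 2-fold lower. B2M ran from -3.12 in SNU398 to 2.14 in SNU387. Of these control genes, 9 of 12 varied between lines beyond the variation of the reference channel, which does not tell lines from single cultures. Those that did not pass the test included ACTB (adjusted p = 0.978) and PPIA (adjusted p = 0.098); the SD of ACTB was 0.84 in the log2 ratio and 0.57 in the reference channel. With the mean over its passing probes ACTB did vary (adjusted p = 4.37e-07), so its call depends on the probe.

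Each line had genes that set it apart. For each line, the gene that exceeded the second-highest line by most was taken. CRH, which encodes a hypothalamic releasing hormone, was 5.27 in PLC/PRF5 (probe A_23_P31755, chromosome 8, 67251315 to 67251374), 9.52 above the next line, SNU423. The potassium channel gene KCNJ16 was 5.62 in SNU449 (probe A_23_P501193, chromosome 17, 65643118 to 65643177), and the protease inhibitor TFPI2 5.12 in JHH1. HAO1, of glyoxylate metabolism, was 4.54 in HUH1, the collagenase MMP1 4.41 in HLE, the phosphatase INPP5D 4.33 in HepG2, the chemokine CXCL1 4.26 in SKHep1 and FAM151A 4.12 in HUH7. The cell cycle inhibitor CDKN1C was 3.87 in Hep3B, and the cyclin CCND2 3.46 in SNU398. The intestinal keratin KRT20 was 3.76 in JHH4, the pancreatic protein REG1A 3.44 in JHH7, the placental PSG1 3.38 in SNU423 and the neurofilament NEFL 3.21 in SNU475. MEDAG was 3.98 in SNU387, RASIP1 3.65 in JHH6, the collagen COL8A2 3.52 in SNU182, MAGEC2 3.38 in HLF, LRRN2 3.19 in JHH2 and the growth factor GDF10 2.77 in JHH5. These genes exceeded the next line by 2.71 (MAGEC2) to 9.52 (CRH). For 5 of them (INPP5D, HAO1, FAM151A, GDF10 and REG1A) the next line was PLC/PRF5, in which the gene was not well above background, so the size of the gap, and the choice of the gene by it, rest on a dim value. HAO1 and GDF10 were well above background in the line channel of 1 line each. Without its own line INPP5D (adjusted p = 0.297) and GDF10 (adjusted p = 0.084) did not pass the test of variance. The SD of the genes taken for the lines in the reference channel, used as the technical error of a single array, was 0.066 (COL8A2) to 0.44 (CCND2).

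The number of genes at least 2-fold from the mix was 1953 (PLC/PRF5) to 3951 (SNU398), with a median of 2915. It was 2-fold higher in 601 (JHH4) to 1421 (SNU398) genes and lower in 1098 (PLC/PRF5) to 2530 (SNU398), and 31.4% of all such changes were upward. That share depends on the scaling. With median centring of each array in place of loess it was 61.7%, and the median log2 ratio of all genes was 0.23 in place of -0.084. Why the share changed was not tested. A gene high in few lines raises the mix and so lies below it in most lines. An excess of values below the mix therefore does not by itself show lowered expression. A line that supplies 1 of 19 equal parts of the mix cannot exceed it by more than 19-fold if both channels respond alike. In 19 lines 0 to 3 genes exceeded 19-fold, AFP in HUH7 among them, and in JHH1, which is not in the mix, 18 genes did. In the 19 lines the sizes of such values cannot be read as exact ratios to the mix.

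HLE and HLF were the most alike of all pairs (r = 0.635 across genes, each gene centred on its mean over lines; genes are not independent replicates; without HLE the highest r was 0.415, without HLF 0.418). Hep3B and HUH7 (r = 0.434), HUH1 and JHH5 (r = 0.432) and JHH5 and JHH7 (r = 0.400) came next, all lines of high hepatocyte score. SKHep1 and SNU423 had r = 0.326. The lowest r was -0.395, between JHH5 and SNU423. JHH1 (0.0766, with SNU182) and SNU398 (0.0868, with PLC/PRF5) had no close partner. JHH1 was alone on its slide and scan day, absent from the mix and on the brightest array, and its distance cannot be told apart from these. The first principal component held 21.7% of the variance, with ALB, APOH and AHSG at its high end and CD44, CAV1, ANXA1 and LOXL2 at its low end. The second held 9.28%, with MTHFD2, PRAME and TWIST1 at the high end and UGT1A6, ACKR3 and FOXA2 at the low end.

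Slides and the mix itself were compared as checks. Over the 5 slides with more than 1 array (19 arrays), 2 genes differed between slides in the log2 ratio and 53 in the reference channel (limma F test, adjusted p under 0.05; 948 and 1400 at an unadjusted p under 0.05). Without PLC/PRF5 421 genes differed in the reference channel. Without any of Hep3B, HepG2, HLE, HLF, HUH1, JHH2, JHH4, JHH5, JHH6, JHH7 or SNU182 22 (HLF) to 35 (JHH2) did. In the log2 ratio 5 genes differed without HUH1, 4 without HUH7 or SNU398, and 1 without any of Hep3B, HepG2, HLE, HLF, JHH2, JHH6, SKHep1, SNU387, SNU423, SNU449 or SNU475. For the 19 lines in the mix, the mean of the linear ratios should be 1 for every gene. Its log2 had a median of 0.074, a 5th percentile of -0.32 and a 95th percentile of 0.42 over 14431 genes, and 98.995% of genes lay within 2-fold.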

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

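The comparison of signal between dim and bright genes and the tests of neighbouring genes were chosen only after the patterns they address had been seen; the counts over other groupings of the lines were planned.

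The report left out 8407 probes that passed the filter on dim probes but carry no usable gene name, of which 7880 varied between the lines and 64 had an SD of the log2 ratio of at least 2. The 3 of largest SD are given because they hold a signal that the comparisons did not use. Probe A_24_P334208 had an SD of 2.81 and was highest in HUH7 at 3.06, but its SD in the reference channel was 1.09, far above the median of 0.17. Probe A_32_P136376 had an SD of 2.71, was highest in HLE at 2.33 and had an SD of 0.0956 in the reference channel. Probe A_32_P171313 had an SD of 2.69, was highest in HLE at 2.12 and had an SD of 0.109 in the reference channel. What these probes measure was not settled. For the latter pair the reference channel, the same RNA 20 times, varied too little to account for the differences between lines.

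PLC/PRF5 had the fewest genes at least 2-fold lower than the mix (1098) and the dimmest array. Compression of ratios near background would be strongest among dim genes. In the third of genes with the highest mean signal, PLC/PRF5 had 617 of 4811 genes at least 2-fold lower and ranked 9 from the lowest of 20, so the low count was not seen among bright genes. The low count is therefore consistent with compression of the ratios on the dimmest array, and no biological explanation was tested.

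Genes that were high in a single line were direct neighbours on a chromosome more often than after shuffling, although most were not. Among 335 genes that exceeded the second-highest line by at least 2 (log2), 19 pairs were neighbours high in 1 line, against at most 5 in 1000 shufflings of gene positions, so chance placement was excluded. Probes that cross-react within gene families account for part at most: without pairs sharing the first 3 letters of their symbols 7 pairs were left, again against at most 5. In SNU182 4 genes in a row on chromosome 17 were high: ZNF18 (2.16), MAP2K4 (2.62), ARHGAP44 (3.19) and ELAC2 (2.58). RBBP7 (2.72) and REPS2 (2.95) on chromosome X were another pair of SNU182. Most of the 7 pairs were of this line, and the count without it was not tested. In JHH1 FBXO8 (4.0) and CEP44 (3.42), and NID2 (4.87) and PTGER2 (4.54), were such pairs, and in HepG2 NOTUM (3.42) and ASPSCR1 (2.92). Family pairs or runs included the PSG genes of SNU423, the CXCL genes and IL1A with IL1B of SKHep1, DLX1 with DLX2 of SNU398 and CYP2A6 with CYP2A7 of HUH1. A gain of DNA or a regulatory region shared by neighbours may lie behind such runs; no DNA was measured, the lines differ in every respect at once, and no biological explanation was tested.

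Of 74 genes at least 3 (log2) below the mix in 1 line only and at least 2 below the second-lowest line, 1 pair were neighbours, PARK7 (-4.80) and ERRFI1 (-5.99) in JHH5. As many pairs arose in 33 of 1000 shufflings (at most 2), and in 32 of 1000 with gene families left out. A loss of DNA there is a candidate explanation that expression alone cannot test. The genes on either side, TNFRSF9 (-1.34) and RERE (-1.06), were lower by less, and no biological explanation was tested. All of these genes were chosen after their values were seen.

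The counts of genes were set against other groupings of the same lines. For the slides, 22 of 100 assignments of the 19 arrays gave at least the 2 genes of the log2 ratio (highest other 41), so chance is not excluded there; whether the assignment with 41 genes reflects a structure among the lines was not tested. In the reference channel 1 of 100, the real one, gave as many as 53 genes (highest other 0), so a random assignment is unlikely to give the difference of the reference signal between slides. For the hepatocyte score no gene was found, and no order of the lines can give fewer than 0, so that 100 of 100 orders did as well within the 13 lines (highest other 1) and 100 of 100 within the 7 lines (highest other 1) says nothing about chance. For the score of hepatic transcription factors 1 of 100, the real one, gave as many as 1067 genes (highest other 4), so a random order of the lines is unlikely to give this count. The 7 and the 13 lines did not overlap in this score, so the test cannot tell the score from the difference between those groups.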

How the results depend on the processing

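The normexp fit on all spots, the multiplier of 2.6, the panel without PLC/PRF5 and JHH1 together and the sum of the lines from the series matrix were chosen after the data had been seen. So was the normexp fit used throughout, made on spots above their background, which replaced limma's default fit after the counts, scores and correlations of the default had been seen.

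The number of genes varying between lines stayed within 1.5 times 13895 under each alternative run, and was 13797 to 14166 with each line left out in turn. With no filter on dim probes it was 15775 of 17431 genes, so dim genes were called as well. The number of lists with a wide spread of scores was 20 to 21 with each line left out. The genes changed per line (2915) were 892 at a 4-fold threshold and 1864 under the default normexp fit. A higher threshold passes fewer genes by construction.

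Relations with an adjusted p under 0.05 (3) were 5 with median centring (54 relations), 5 with the mean over probes and 1 to 5 with each line left out. With each slide centred 6 passed, adjusted over 32 relations in place of 55. The permutation p-values there did not allow for the slide means removed and are too small, so 6 may be too many. The r of AFP and ALB changed sign to -0.029 with median centring; the cause was not tested. The highest correlation between lines (0.635) joined HLE and HLF throughout the alternatives of processing. It was 0.620 by Spearman, 0.698 over the 1000 genes of largest SD, 0.628 without PLC/PRF5 and JHH1, 0.638 with median centring, 0.631 with no filter, 0.641 under the strict filter, 0.547 under the default normexp fit and 0.632 with the multiplier of 2.6. It was 0.415 to 0.644 with each line left out, lowest without HLE, since the pair is then gone. The lowest correlation (-0.395) was -0.350 by Spearman, -0.480 over the 1000 genes, -0.405 without JHH1, -0.410 without PLC/PRF5 and JHH1, -0.414 with median centring, -0.409 under the strict filter, -0.351 under the default normexp fit, and -0.412 to -0.355 with each line left out. The pair was JHH5 and SNU423 except under the default normexp fit (JHH5 and SKHep1) and without JHH5 or SNU423 (Hep3B and HLE).

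The median of the summed lines against the mix (0.074) was 0.064 over probes well above background on all 19 arrays, 0.18 with the scanner's processed signals, 0.18 with the series matrix, 0.46 with median centring, 0.071 with no filter, 0.064 under the strict filter, 0.077 with the mean over probes and 0.062 under the default normexp fit. Median centring sets the median of all probes, dim ones included, to 0; the cause of these shifts was not tested. The 5th and 95th percentiles (-0.32 and 0.42) were -0.24 and 0.54 with the scanner's processed signals, -0.24 and 0.54 with the series matrix, -0.055 and 0.95 with median centring, -0.30 and 0.39 with no filter, -0.28 and 0.39 with the mean over probes, -0.26 and 0.33 under the default normexp fit and -0.31 and 0.40 with the multiplier of 2.6. The 95th was 0.55 over probes well above background on all 19 arrays and 0.43 under the strict filter, and the 5th was -0.33 without PLC/PRF5 and JHH1.

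The genes associated with the hepatocyte score in the 13 lines (0) were 33 under the default normexp fit, 1067 with the hepatic transcription factor score over 20 lines, and 0 to 1 with each line left out; in the 7 lines they were 0 to 0. The transcription factor fit changes both the score and the lines, and the cause was not tested for it or for the 33 genes. Lists moving with the score (5 and 6) were 0 and 0 with an estimated correlation, which widens the error of each list by construction. In the 13 lines they were 8 with slide as a block, of which 2 (cancer-testis and metabolic) were among the 5 and 6 were others, and 2 to 7 with each line left out. In the 7 lines they were 3 without PLC/PRF5 and JHH1 and 3 to 6 with each line left out. NRF2 targets in the 7 lines changed sign with slide as a block (median t 0.46). That slope rests only on HUH1 with JHH7 and HUH7 with PLC/PRF5, the lines that share a slide. The cause was not tested further.

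Genes differing between slides in the log2 ratio (2) were 1 under the strict filter, 1 under the default normexp fit and 1 to 5 with each line left out. In the reference channel (53) they were 16 with median centring, 29 with the mean over probes, 34 under the default normexp fit, 421 without PLC/PRF5 and JHH1, and 22 to 421 with each line left out. The highest count was without PLC/PRF5, the dimmest array; the cause was not tested.

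With the mean over members in place of the median, scores changed sign for the plasma proteins in PLC/PRF5 (-0.29) and the mesenchymal list in JHH2 (-0.45), SKHep1 (-0.21) and SNU475 (-0.0031); the cause was not tested. The endothelial score of JHH6 was -0.041 with no filter and -0.041 with the multiplier of 2.6. Of the other alternatives for the scores of lists in lines given in the report, 442 moved by less than the SD of the reference channel and 242 by more. For genes in lines these numbers were 925 and 216. Median centring moved the most, 57 of 69 scores and 109 of 129 genes, and no filter and the multiplier of 2.6 moved none of the 129 genes. Of named genes, 3728 alternatives kept their call of variation, 2 lost it and 1 gained it.

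No paired analysis was made, because each line was measured once and the labels used name no 2 lines as a pair. All lines were treated as independent, although HLE and HLF (r = 0.635) were more alike than the next pair (r = 0.434). The relations of HNF4A with AFP and ALB were not run because HNF4A failed the filter. Leaving out JHH1 leaves the slide tests unchanged, since it is alone on its slide. Signal over background limits the log2 ratios of dim genes, most on the PLC/PRF5 array, where 34.8% of spots were well above background in the line channel.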

Other observations

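The JHH1 line, which is absent from the mix, had 48 genes at least 2 (log2) above the second-highest line, the most of all lines, followed by SNU182 with 45. JHH1 was also alone on its slide and scan day and on the brightest array, which cannot be told apart from the line itself.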
